A study of Mus musculus with 2 samples.

How the data were processed

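Accessible chromatin was measured by ATAC-seq, the assay for transposase-accessible chromatin, in which the Tn5 transposase inserts sequencing adapters into DNA that is not shielded by nucleosomes. Per the labels, the tissue was lung of healthy mouse embryos of the strain B6NTac;B6NCrl/Lap at embryonic day 14.5 (E14.5), with males and females pooled, and the libraries were made by Nextera tagmentation. The series held 1 group of 2 biological replicates. Replicate 1 was a pool of lungs from 17 embryos and replicate 2 a pool from 34 embryos. No second tissue, age or treatment was part of the design, so the comparisons made were between the replicates, between classes of genomic sequence, and between fixed gene lists and matched random genes.

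The deposited files were peak lists on the mouse genome build mm10, made from filtered alignments per the labels. The aligner, the peak caller, its settings and any shift of read positions for the transposase were not given in the sources used here. Each entry of a list is 1 summit, and a region with several summits is repeated once per summit. The fold enrichment of each peak, a ratio of the peak to its local background, is the authors' deposited value and was used to describe, rank or choose peaks within its own list, and to choose the 10 named genes open in 1 replicate only, which ranks the lists of both replicates together. The −log10 p and −log10 q values per peak were likewise deposited by the authors, and the −log10 of the irreproducible discovery rate (IDR, the expected share of peaks that would not recur between replicates) stood in the deposited ranked list that compares the replicates. No control library was named, and read counts per library were not part of the files used here. The depth of each library is therefore unknown, and no interval or limit of detection that needs it was given.

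For each replicate, the list of pseudoreplicated peaks, called on that replicate alone, was the main list. For both replicates together, the list of conservative IDR thresholded peaks, called on pooled reads and kept by the comparison of the replicates, was the main list of reproducible regions. Overlapping or repeated entries were merged to regions, each placed at its strongest summit, and only regions on chromosomes 1 to 19, X and Y were kept. A region's fold enrichment is that of its strongest summit, which can lie outside a promoter that the region overlaps. Coordinates are given 1-based on mm10.

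Regions of the replicates were called shared when they overlapped by at least 1 bp. The shares were set against 100 circular shifts of the other list along each chromosome, and their exact (Clopper-Pearson) 95% binomial intervals cover counting error only. Peak strength was compared with Spearman's rho and Pearson's r of log2 values over the summits of the ranked list that holds a −log10 p for both replicates. The planned measure was the fold enrichment, which that list does not give per replicate, so the −log10 p was used in its place. Its columns carry no replicate name. They were called replicate 1 and replicate 2 because 99.1% of the values of the 1 column recurred in the ranked list of replicate 1 and 98.5% of the other in that of replicate 2, against 35.3% and 36.4% for the opposite assignment. Correlations run across summits, which are not independent replicates, so no p was given.

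Genes were taken from the GENCODE mouse release M21 basic annotation, with 77221 transcription start sites (TSSs) of genes of all types and 21911 protein-coding genes. A promoter ran from 1000 bp upstream to 100 bp downstream of a TSS. Regions were assigned by their summit to promoter, exon, intron or intergenic sequence, in that order, and compared with 100 circular shifts. A promoter was called open where a reproducible region overlapped it. Distal regions were those with a summit outside the promoters of all genes, counted per gene within 50 kb of any of its TSSs. A region that overlaps a promoter but has its strongest summit outside counts both as an open promoter and as distal, as at Hoxa5 and Hoxb4. With a promoter of 1000 bp to either side, 13074 of the 27295 reproducible regions had a promoter summit, against 11631. Distal counts and motifs were not rerun with that promoter. A gene with widely spread TSSs is therefore counted over more sequence.

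Before the data were examined, 21 lists of marker or pathway genes were fixed: lung epithelial progenitors, alveolar epithelium, airway epithelium, lung mesenchyme, smooth muscle, endothelium, mesothelium, leukocytes, the erythroid lineage, nerve and neural crest, cardiac muscle, liver, forebrain, skeletal muscle, germ cells, photoreceptors, housekeeping genes, anterior Hox genes (paralogues 1 to 5), posterior Hox genes (paralogues 9 to 13), hedgehog, WNT, FGF and BMP signalling, and retinoid, Notch and Hippo signalling. The 1464 olfactory and vomeronasal receptor genes formed a further list as a control. All 375 symbols of the 21 lists matched the annotation. Each list was compared with 10000 random lists of protein-coding genes of the same size, matched on gene length class (5 classes) and on promoter CpG class (observed over expected CpG of at least 0.6 within 500 bp of the TSS, or below). Two-sided permutation p-values were adjusted by the Benjamini-Hochberg method over the 22 lists, and the smallest p these permutations can give is 1e-04. Genes are not replicates, so these tests describe the libraries at hand. The permutation test of distal regions was run on simulated lists of 20 genes drawn at random from the 21911. At an unadjusted p below 0.05 it called 4.00% at no change, 37.5% of lists with a planted 1.5-fold excess, 71.0% at 2-fold and 96.5% at 3-fold. Calls on the 22 lists use the adjusted p, which is stricter, and the simulation does not cover lists of neighbouring genes.

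Matches of 24 fixed consensus motifs were counted within 100 bp of the summits of distal reproducible regions and in windows of the same size centred 1000 bp to either side, leaving out flanks in another reproducible region. The ratio of both shares was divided by the median ratio of 20 shuffled versions of the motif, or of those that matched any flank (14 for RFX), to allow for base composition. Shuffling does not keep pairs of neighbouring bases such as CpG. The 95% interval of the divided ratio came from 1000 bootstrap draws of regions and leaves out the spread of the shuffled versions. A motif was called higher or lower where the interval lay apart from 1 and at least 10 flanks held a match, a minimum set after the data were seen.

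The genes named in the text were fixed beforehand: 36 genes, the 3 members of each list with the most distal regions, the 10 genes with the most distal regions in the genome, the 10 regions with the highest fold enrichment, and the 10 genes open in 1 replicate only with the strongest promoter region. Others are named as chosen after their values were seen. The alternatives tried were the IDR thresholded and replicated lists, a q of at most 1e-05, an IDR of at most 0.01, overlap of at least 50% of both regions, equal numbers of regions, a promoter of 1000 bp to either side, distal windows of 10 and 100 kb, matching on gene length alone, a motif window of 50 bp to either side, motifs with promoters included, and each replicate left out in turn, for which the IDR thresholded list of the other replicate was used. Further alternatives were added after the data were seen: every summit counted, random lists without olfactory and vomeronasal receptor genes, random lists also matched on the number of genes within 50 kb, and each region counted once per list. A pooled pseudoreplicated list and a ranked list made from it were not used here. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, pyfaidx 0.9.0.4, bedtools 2.31.1 and blastn 2.17.0 were used, with random seed 1.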

Results

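Open chromatin of the embryonic mouse lung was profiled by ATAC-seq at E14.5, an age at which branching epithelial tubes grow into a surrounding mesenchyme. The 2 biological replicates of the single group were pools of lungs from 17 embryos (replicate 1) and 34 embryos (replicate 2). Both replicates together gave 27295 reproducible accessible regions with 73723 summits, which covered 27.9 Mb of mm10 and had a median width of 1011 bp. Called alone, replicate 1 had 82223 regions over 52.1 Mb and replicate 2 had 47915 regions over 28.3 Mb (their main lists), so that replicate 1 had 1.72 times as many. The number of reads behind each library is unknown, since the peak lists carry no read counts, and each list is a single value without an SD.

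Promoters of marker genes were compared first with those of matched random genes, and are called open where a region overlaps them. A promoter without a region was not detected as open, which does not show that it was closed. Genes of the lung mesenchyme and of smooth muscle had open promoters more often than matched random genes, with 23 of 25 mesenchymal genes (92.0% against a random mean of 64.2% ± 7.37, SD of 10000 lists) and 14 of 15 smooth muscle genes (93.3% against 43.5% ± 11). Among the mesenchymal genes, Fgf10, the growth factor of the distal mesenchyme that drives bud outgrowth, had a promoter region with a fold enrichment of 4.73 (4.99 in replicate 1 and 4.53 in replicate 2). The transcription factor genes Tcf21 (5.45), Foxf1 (5.92), Tbx2 (7.48) and Tbx4 (4.61) were open too, as was Gli1 (3.30), a target of hedgehog signalling. The exceptions were Wnt5a, named after its value was seen, and Tbx5, whose promoter had a region in each replicate's main list (2.67 and 2.21) but not in the reproducible list. Smooth muscle promoters included Acta2, encoding smooth muscle actin (7.57), and Myocd, encoding the coactivator of the smooth muscle programme (9.31), while Cnn1, named after its value was seen, was the only one without a region. The adjusted permutation p was 9.4e-04 for mesenchyme and 3.7e-04 for smooth muscle. Both calls were lost at a stricter IDR of 0.01 (72% against 58.8% for mesenchyme and 60% against 37.8% for smooth muscle, adjusted permutation p of 0.157 and 0.111). They were also lost in the IDR thresholded list of replicate 2, where mesenchyme had 60% against 55.8% and smooth muscle 53.3% against 34.5% (adjusted permutation p of 0.670 and 0.173), although the longer main list of replicate 2 had regions at all 25 and all 15 promoters.

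Promoters of 5 lists were open less often than those of random genes, and each had an adjusted permutation p of 3.7e-04, from the smallest p of 1e-04 that the permutations can give. Posterior Hox genes and olfactory and vomeronasal receptor genes lie in clusters, so their p-values, here and for distal regions, can be too small. Olfactory and vomeronasal receptor genes had 2 open promoters of 1464 (0.137% against 17.2% ± 0.875), those of Olfr658 and Vmn1r4. Posterior Hox genes, which pattern the posterior body and the limbs, had 2 of 16 (12.5% against 67.8% ± 8.62), and germ cell genes had 2 of 15 (13.3% against 52.4% ± 8.53), Dazl and Tex14, with no region at Ddx4. Of the forebrain genes 5 of 17 were open (29.4% against 72.7% ± 7.64), among them the transcription factor genes Lhx2 (10.6) and Bcl11b (4.93), and Emx1, Pax6 and Satb2, while Neurod6 had no region in either replicate. Endothelial genes had 6 of 22 open promoters (27.3% against 59.2% ± 8.31). Kdr, encoding a receptor of vascular growth factor, was open (8.20), as were Esam (3.49) and Egfl7 (4.96), whereas Pecam1, an adhesion molecule of endothelial cells, had no promoter region in any replicate. The endothelial call depended on the peak list, since 17 of the 22 promoters held a region in the main list of replicate 1 and 15 in that of replicate 2, including Cdh5 at a fold enrichment of 2.47 and 2.5. With the replicated peaks, a longer list, the share was 86.4% against 68.9% in random lists (adjusted permutation p = 0.0764), and in the IDR thresholded list of replicate 1 it was 40.9% against 60.4% (0.0576). With the replicated peaks 3 other calls held but lay closer to random lists, with posterior Hox genes at 50% against 74.9%, forebrain genes at 58.8% against 79.3% and germ cell genes at 26.7% against 59.5% (adjusted permutation p of 0.0158, 0.0185 and 0.00495). With random lists matched on gene length alone, the forebrain and posterior Hox calls were lost (adjusted permutation p of 0.0610 and 0.0805). Genes named here and further on for a count of 5 or fewer, beyond the fixed rule, were chosen after their values were seen.

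Epithelial lists did not pass the test at promoters, except that progenitor genes did against random lists matched on gene length alone (87.5% against 50.9%, adjusted permutation p = 4.4e-04). Of the lung epithelial progenitor genes 21 of 24 were open (87.5% against 79.7% ± 6.51), among them Sox9 (7.36), a marker of the distal tips, Sox2 (8.0), a marker of the proximal airway, Foxa2 (5.24) and Etv5 (12.8). The 3 without a region were Shh, Cldn6, named after its value was seen, and Nkx2-1, the main regulator of lung identity, whose promoter had a weak region in each replicate's main list (3.21 and 4.08). Alveolar genes had 10 of 20 open promoters and airway genes 9 of 20. The surfactant gene Sftpc and the secretory cell gene Scgb1a1 had no promoter region in either replicate, Sftpb was open in each replicate's main list (5.51 and 4.37), and Foxj1, the regulator of ciliated cells, was open in the reproducible list (9.35). The mesothelial genes had 6 of 12 open promoters, with Upk3b open (4.54) and Wt1 open only in the replicates' main lists (6.59 and 3.40).

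The other lists did not pass the test at promoters in the reproducible list either. Leukocyte genes had 3 of 18 open promoters, those of Runx1 (9.37), Ikzf1 and Coro1a, with no region at Ptprc and Spi1. Erythroid genes had 2 of 16, Ank1 and Gypa, with no region at Gata1. Nerve and neural crest genes had 6 of 14, with Ednrb open (5.64) and no region at Phox2b. Cardiac muscle genes had 2 of 14, Actc1 and Ryr2, with no region at Nkx2-5, and skeletal muscle genes 2 of 14, Myf5 and Mylpf (10.4), with no region at Myod1. None of the 16 liver genes was open, Alb included, nor any of the 13 photoreceptor genes, Rho included. All 20 housekeeping promoters were open, for example Actb (5.32) and Polr2a (9.84). Anterior Hox genes had 8 of 15 open, hedgehog, WNT, FGF and BMP signalling genes 25 of 27 (all but Fgf7 and Grem1), and retinoid, Notch and Hippo genes 18 of 22 (all but Rxra, Crabp1, Rbp1 and Stra6). Over these lists and the epithelial and mesothelial ones, the adjusted permutation p ranged from 0.0721 for liver and housekeeping genes to 1.00. Nerve and neural crest genes were lower than random in each replicate's IDR thresholded list (21.4% against 55.4% in replicate 2, adjusted permutation p = 0.00660, and 35.7% against 64.2% in replicate 1, 0.0299). Housekeeping genes passed as higher at an IDR of 0.01 and in the IDR thresholded list of replicate 2 (adjusted permutation p of 0.0377 and 0.0179), and photoreceptor genes as lower with the replicated peaks (0.0158). With random lists matched on gene length alone, housekeeping genes and hedgehog, WNT, FGF and BMP genes passed as higher, and leukocyte, erythroid, cardiac muscle, skeletal muscle, liver and photoreceptor genes as lower (adjusted permutation p from 4.4e-04 to 0.00626). Mesothelial genes were lower in the IDR thresholded list of replicate 2 (8.33% against 52.0%, adjusted permutation p = 0.00176, with 8 of 12 open in its main list) and at an IDR of 0.01 (25% against 54.4%, 0.0363).

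Distal regions, the class that holds most enhancers, were more numerous around genes of the signalling lists and of lung mesenchyme than around matched random genes. No second tissue was measured, so whether this is particular to lung was not tested. The counts cover all annotated TSSs of a gene, and random lists were not matched on the number or spread of TSSs. Hedgehog, WNT, FGF and BMP signalling genes had 2.78 distal regions per gene within 50 kb against 1.07 ± 0.253 in random lists, 2.60 times as many. Nkd1, a feedback inhibitor of WNT signalling, and Id1, a target of BMP signalling, each had 7, and Smad7 had 6. Retinoid, Notch and Hippo genes had 2.77 against 1.09 ± 0.282, 2.54 times as many, with 8 near the retinoid X receptor gene Rxra and 7 each near Tead1, encoding a partner of the Hippo effector YAP, and the retinoic acid receptor gene Rara. Lung mesenchyme genes had 1.96 against 0.986 ± 0.253, 1.99 times as many, with 5 near Tbx2 and 4 each near the hedgehog receptor gene Ptch1 and the collagen gene Col1a1. The adjusted permutation p was 5.5e-04 for both signalling lists and 0.00396 for mesenchyme. All 3 lists passed the test under every alternative run on distal regions. The promoter of 1000 bp to either side was not among these, so regions with a summit more than 100 bp downstream of a TSS stayed in the counts. Within 10 kb their ratios were larger, at 3.97, 4.83 and 3.29 in the same order.

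Distal counts of 2 further lists were above random, each with a limit. Anterior Hox genes had 3.27 distal regions per gene against 1.01 ± 0.344 (adjusted permutation p = 5.5e-04), with 6 near Hoxb1 and 5 each near Hoxb4 and Hoxb5. These genes lie side by side and share regions. Counted once per list, their 14 distinct regions gave a ratio of 0.926 to random lists (adjusted permutation p = 0.991). Photoreceptor genes had 1.85 against 0.774 ± 0.333, 2.39 times as many (adjusted permutation p = 0.0224), although no photoreceptor promoter was open. Gnat1 had 8 and Rho 6 of the 24 regions, and Cngb1 had 2. This call was lost in a 10 kb window (2.96 times, adjusted permutation p = 0.0522), at an IDR of 0.01 (1.92 times, 0.245), in the IDR thresholded list of replicate 2 (2.05 times, 0.158), and against random lists without olfactory and vomeronasal receptor genes (2.05 times, 0.0517). Olfactory and vomeronasal receptor genes had 0.0943 distal regions per gene against 0.719 ± 0.0281 (adjusted permutation p = 5.5e-04), and the exceptions with the most were Olfr1423 with 8 and Olfr1368 and Olfr263 with 7 each.

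The remaining lists did not pass the test for distal regions (adjusted permutation p from 0.121 to 1.00). Smooth muscle genes had 1.75 times as many as random lists, with 4 each near Synpo2 and Mylk, and endothelial genes 1.59 times as many, with 5 near Esam and 4 near Egfl7. Both passed within 10 kb (2.85 times, adjusted permutation p = 0.0361, and 2.63 times, 0.0187) and in the replicated list (2.40 times, 3.7e-04, and 1.77 times, 0.00314). In the IDR thresholded list of replicate 1 both also passed (1.87 times, adjusted permutation p = 0.0344, and 1.77 times, 0.0185). Lung epithelial progenitor genes had a ratio of 1.22, led by Id2 with 4 and Fgfr2 and Etv4 with 3 each. Alveolar genes had 1.37, with 5 near Ctsh, and airway genes 1.28, with 4 near Tppp3. In the replicated list these 3 ratios passed the test at 1.39 (adjusted permutation p = 0.0445), 1.64 (0.0129) and 1.53 (0.0244), and so did skeletal muscle at 1.73 (0.0244) and erythroid genes at 1.77 (0.0196), so this gain was not particular to lung cell types. The others were skeletal muscle (1.73, with 6 each near Mymk and Tnnt3), housekeeping genes (1.49, with 6 near Ubc, passing at 1.83 with matching on gene length alone, adjusted permutation p = 0.0403), erythroid genes (1.39, with 4 near Nfe2) and leukocyte genes (1.36, with 3 near Spi1). Cardiac muscle stood at 1.28 (Mybpc3 and Tnni3 with 3 each), germ cells at 1.12 (Zp2 with 3), mesothelium at 1.11 (Upk1b with 3) and forebrain at 1.07 (Slc17a7 with 3). Liver had a ratio of 0.992 (Nr1h4 with 3), nerve and neural crest 0.864 (Ednrb with 4) and posterior Hox genes 0.724 (Hoxb9 with 4).

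**Figure D1:**
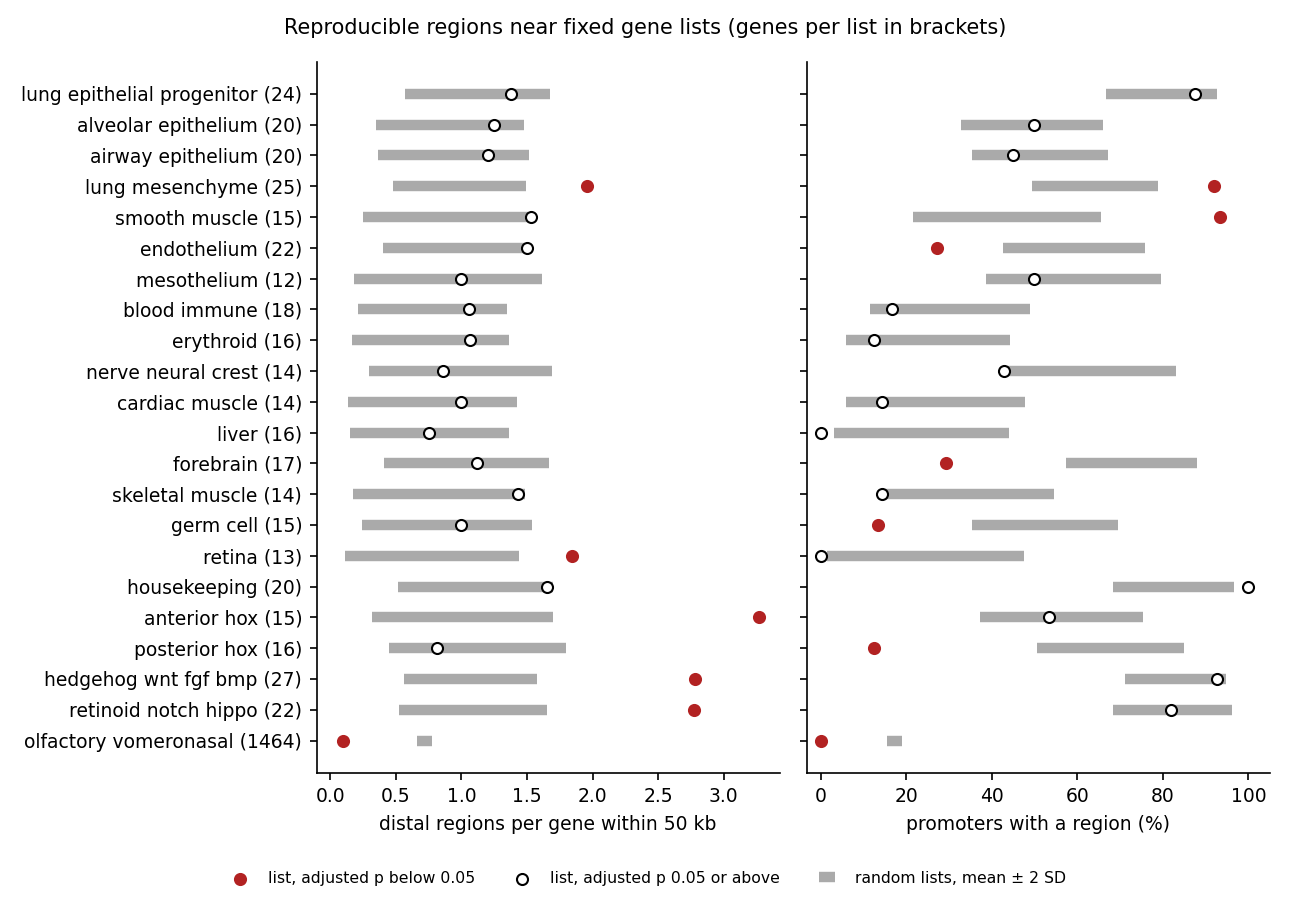
Mean number of distal reproducible regions per gene within 50 kb (left) and percent of promoters with a reproducible region (right) for each gene list, with the number of genes in brackets. Points are the lists, filled where the adjusted permutation p was below 0.05, and grey bars are the mean ± 2 SD of matched random lists; lung mesenchyme stands above its bar in both panels, at 1.96 distal regions per gene and 92.0% of promoters.

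The genes with the most distal regions in the whole genome were led by Mecom, encoding a zinc finger transcription factor, with 11 within 50 kb of its TSSs. Trim27, the amino acid transporter gene Slc38a3 and the corepressor gene Ncor2 had 10 each. Prss16, Pom121l2, the corepressor gene Bcor, the imprinted gene Dlk1 and the Fc receptor gene Fcgr3 had 9 each, and Osbp had 8. Others, such as Rxra and Gnat1, had 8 too, and Osbp took the last place by the fold enrichment of its promoter region. Slc38a3 and the photoreceptor gene Gnat1 are neighbours on chromosome 9, at 107650634–107669530 and 107674474–107679712. Trim27 (chromosome 13, 21179445–21194724) lies beside the receptor genes Olfr1368 and Olfr263 (21141882–21145867 and 21129639–21136296). Neighbours in this ranking thus count some of the same regions.

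The Hoxa and Hoxb clusters were looked at in detail, without a test of position. The Hoxa cluster on chromosome 6 held 8 reproducible regions, the strongest at Hoxa5, a gene needed for lung and trachea development, at 52203969–52204863 with a fold enrichment of 7.09 (6.40 in replicate 1 and 7.74 in replicate 2 for the promoter's region in each list). It was also the last of the 8 along the chromosome, and no reproducible region lay from Hoxa6 to Hoxa13. The promoter of Hoxa13 had a region in the main list of replicate 1 only (7.46). In the Hoxb cluster on chromosome 11, 6 regions lay from 96285221, at the end of Hoxb8, to 96333214 within Hoxb3. The strongest was at Hoxb4 (96318084–96319031, fold enrichment 6.47). No region lay over the bodies of Hoxb1, Hoxb2, Hoxb6, Hoxb7, Hoxb9 or Hoxb13. The 2 open posterior Hox promoters, named after their values were seen, were those of Hoxc13 and Hoxd10.

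**Figure D2:**
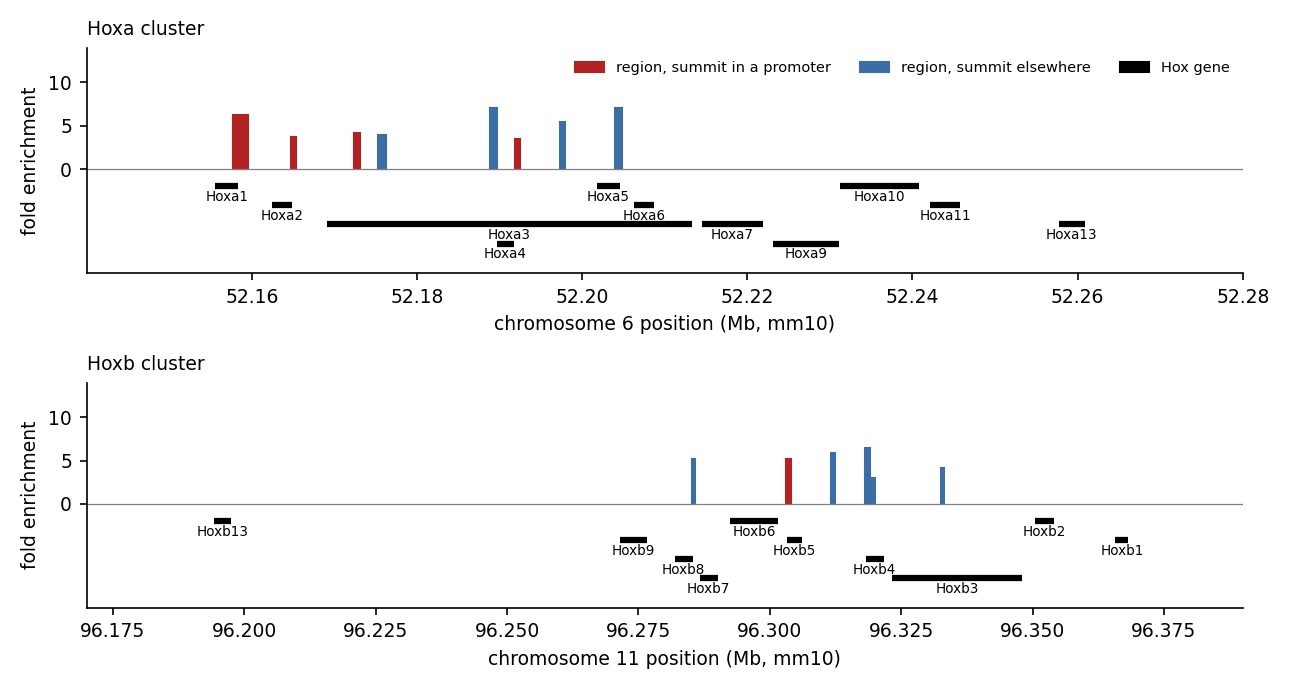
Reproducible regions of the Hoxa cluster (top) and the Hoxb cluster (bottom) by position in Mb on mm10, with the height of each bar its fold enrichment and black lines the Hox genes. Bars are coloured by whether the strongest summit lies in a promoter; the 8 Hoxa regions end at Hoxa5, and none lies over Hoxa6 to Hoxa13.

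Short sequence motifs bound by transcription factor families were compared between the summits of 15623 distal regions and their flanks. Of the 24 motifs, 14 had a higher ratio of summits to flanks than the median of their shuffled versions. The TEAD motif, bound by the nuclear partners of YAP, lay within 100 bp of 8.10% of summits against 3.33% of flanks, 3.08 times the shuffled motifs (95% bootstrap interval 2.85–3.35). The E-box bound by TCF21 and related factors reached 3.72 (3.15–4.45), the MEF2 motif of muscle genes 4.29 (3.20–5.73) and the forkhead motif 2.02 (1.91–2.14). The forkhead motif lay at 11.2% of summits against 8.65% of flanks, and with promoters included at 7.86% against 8.62%. The grainyhead motif of epithelial cells had a ratio of 4.59 (2.40–10.5) on 35 regions. The RFX motif, bound by regulators of ciliated cells among others, had the highest, 14.3 (8.92–26.2), on 99 regions. The others above 1 were KLF and SP (2.18), ETS (1.88), AP-1 (1.69), CTCF (1.60), GATA (1.59), PU.1 (1.59), OCT (1.25) and SOX (1.18). Of these, OCT lay at fewer summits than flanks (0.819% against 1.11%), and SOX (6.59% against 6.68%) and GATA (4.22% against 4.20%) at about as many, so their excess is over the shuffled versions only. The shuffled versions of a motif varied, and the motif exceeded all 20 of them for the forkhead, GATA, ETS, TEAD, AP-1, KLF and SP, MEF2 and grainyhead motifs. RFX exceeded all 14 of its versions that matched any flank. Of 20, the motif exceeded 19 for the TCF21 E-box and PU.1, 18 for CTCF, 15 for SOX and 14 for OCT.

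The NK2 motif, bound by NKX2-1 among others, was lower than its shuffled versions, at 0.755 (0.686–0.828), with 3.78% of summits against 3.81% of flanks. The T-box motif stood at 0.768 (0.613–0.924) and the TFAP2 motif at 0.624 (0.552–0.695), although TFAP2 lay at more summits than flanks (4.74% against 1.74%). The NK2, T-box and TFAP2 motifs exceeded 6, 4 and 3 of their 20 shuffled versions. The proneural E-box (1.11), CRX and OTX (1.07), RUNX (1.05) and HNF4 (0.855) had intervals that included 1. Of these, CRX and OTX passed as higher at an IDR of 0.01 (1.56, 1.06–2.25) and the proneural E-box in the IDR thresholded list of replicate 1 (1.26, 1.15–1.38). HNF4 passed as lower within 50 bp of the summits (0.713, 0.537–0.924), and the proneural E-box with promoters included (0.914, 0.837–0.995). The NFI, NRF1 and HNF1 motifs matched too few flanks for a ratio, with 36, 28 and 8 regions. CTCF turned to 0.726 (0.653–0.813) when promoter regions were included, while ETS rose to 5.34 and OCT to 2.03. CTCF still lay at more summits than flanks there (5.09% against 0.834%), so it was lower than its shuffled versions only. The RFX and grainyhead calls were lost where fewer than 10 flanks held a match, within 50 bp of the summits and in the IDR thresholded list of replicate 2, and grainyhead also at an IDR of 0.01. The OCT call was lost in the IDR thresholded list of replicate 1 (1.1). Within 50 bp of the summits the ratios of CTCF and MEF2 were 2.52 and 7.48, and in the IDR thresholded list of replicate 2 that of PU.1 was 2.40.

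**Figure D3:**
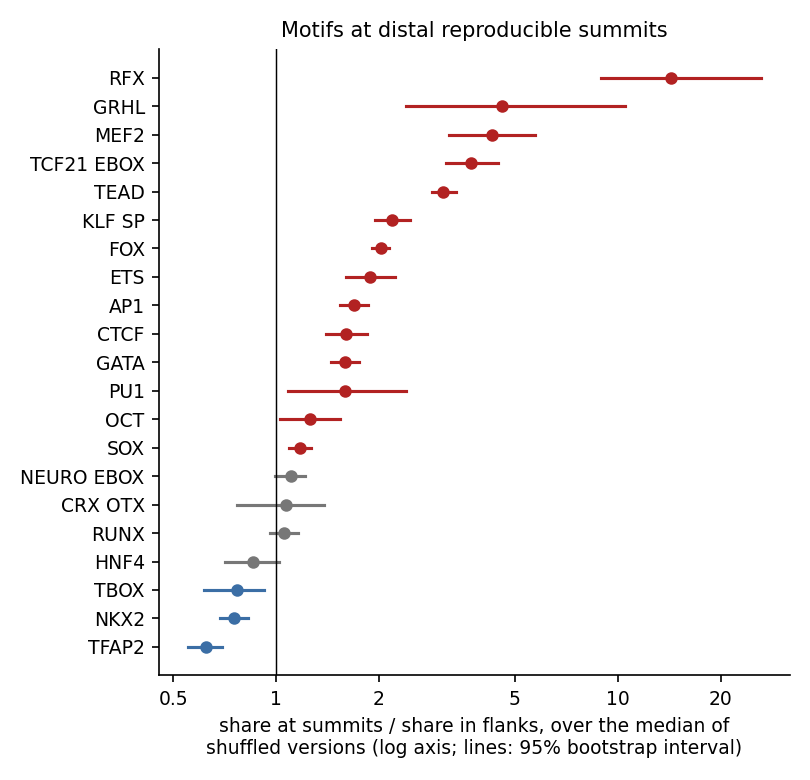
Ratio of motif frequency at the summits of distal regions to that in their flanks, divided by the median of the shuffled motifs, with 95% bootstrap intervals on a log axis. TEAD lies at 3.08 and the forkhead motif at 2.02. The NK2 motif lies at 0.755, although its shares at summits and in flanks are close (3.78% and 3.81%). Motifs with under 10 flank matches carry no call.

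Promoters made up 42.6% of the reproducible regions (11631, 95% exact binomial interval 42.0–43.2%), 16.3 times the 2.62% ± 0.108 (SD of 100 shifts) found when the regions were shifted along their chromosomes. Exons held 5.36% (1.43 times the shifted share), introns 28.6% (0.663 times) and intergenic sequence 23.4% (0.464 times). By their strongest summit, promoter regions also had the highest median fold enrichment, 9.90 against 6.91 in exons, 6.56 in introns and 6.89 in intergenic sequence. With every summit counted the gap was smaller, with medians of 5.79 against 4.12, 4.11 and 4.76 in the same order. The promoter share followed how many weak regions a list holds, and was 20.8% among the 71803 replicated regions and 60.1% among the 16822 IDR thresholded regions of replicate 2. Chromosome 11 was the densest, with 15.9 reproducible regions per Mb. Chromosome X had 4.07 per Mb and chromosome Y held 5 regions.

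**Figure D4:**
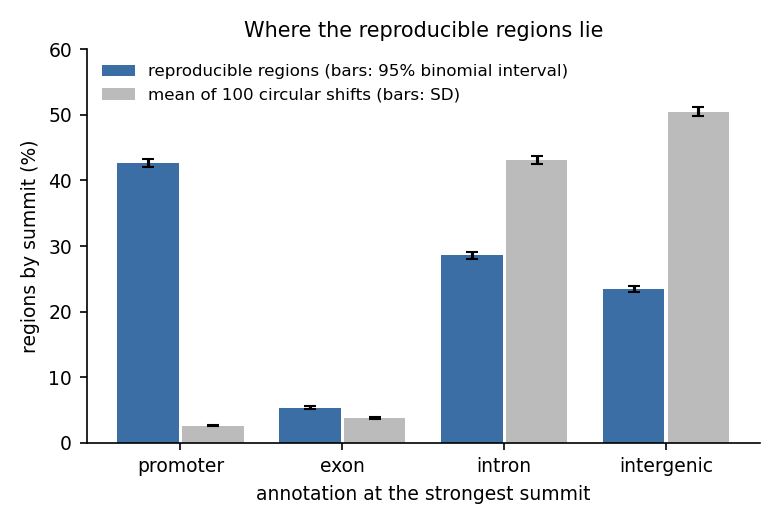
Percent of the 27295 reproducible regions with their strongest summit in promoters, exons, introns and intergenic sequence, beside the mean of 100 circular shifts. Promoters hold 42.6% against 2.62% after shifting, while introns and intergenic sequence hold less than their shifted shares.

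The replicates shared nearly all strong regions and differed in the weak ones. Of the replicate 2 regions, 91.3% (95% exact binomial interval 91.0–91.5%) overlapped a region of replicate 1, against 3.92% after shifting. Of the replicate 1 regions, 51.1% (50.8–51.5%) overlapped one of replicate 2, against 2.29% after shifting. When the regions of replicate 1 were ordered by strength in 5 equal groups, 15.2% of the weakest group (median fold enrichment 2.68) and 96.9% of the strongest (9.97) were found in replicate 2. The corresponding shares of replicate 2 regions found in replicate 1 were 75.2% and 99.97%. With equal numbers of the strongest regions the shares were 73.1% for replicate 1 and 77.3% for replicate 2. Across the 149329 summits with a −log10 p in both replicates, Spearman's rho was 0.644 and Pearson's r of log2 values 0.744, and over the 115840 distal summits rho was 0.551. The −log10 p was higher in replicate 1 at 79.7% of summits.

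**Figure D5:**
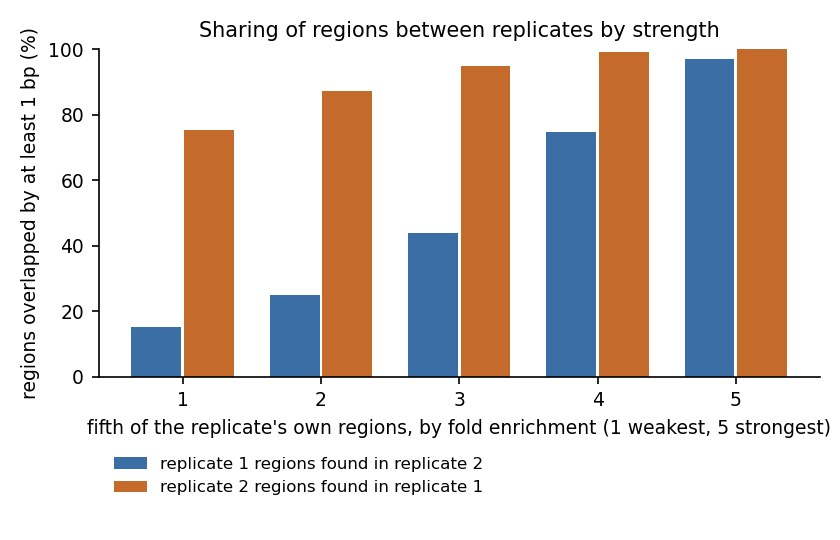
Percent of each replicate's regions that overlap a region of the other replicate by at least 1 bp, in 5 equal groups ordered by fold enrichment within their own list. The share rises from 15.2% to 96.9% for replicate 1 and from 75.2% to 99.97% for replicate 2.

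Whether marker promoters differed between the pools was asked of all 21911 protein-coding genes. A promoter region was present in 14382 genes in replicate 1 and 13420 in replicate 2, of which 13342 were shared. Another 1040 genes were open in replicate 1 only and 78 in replicate 2 only. The regions at these promoters were weak, with a median fold enrichment of 3.73 and 3.34, against 9.69 in replicate 1 at shared promoters. On equal numbers of the strongest regions the counts were 488 and 546, so the excess in replicate 1 did not hold at matched list length. Each pool is 1 library, so the difference was not tested. The 10 with the highest fold enrichment in the list of their own replicate, a choice that sets both lists side by side, were open in replicate 1, and none was on a marker list: 1700017N19Rik (18.5), Cpeb4 (17.6), Sap30bp (17.3), Slc35f4 (15), Tmem207 (12.1), Gm4969 (12), Wdr4 (12), Sntg1 (11.9), Erich2 (11.8) and Crispld1 (11.7). Each value is that of the region's strongest summit, which can lie outside the promoter. Whether replicate 2 had a region beside these promoters was not examined. Of the listed genes, 7 of 1464 olfactory and vomeronasal receptor genes and 6 of 16 posterior Hox genes were open in replicate 1 only. So were 4 each of the forebrain and nerve genes and 3 each of the airway and endothelial genes. Among the markers open in replicate 2 only was Hbb-bt, an adult β-globin gene (6.47).

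The 10 strongest reproducible regions were mostly narrow intergenic sites. The highest fold enrichment, 55.8, lay at chromosome 2, 69355469–69355735, 12987 bp from the nearest TSS, that of Abcb11. The next was 54.4 on chromosome X at 143482936–143483180, 35531 bp from Pak3. The region on chromosome 16 at 17222207–17222580 (29.5) lay 11208 bp from Hic2. The other 7 had a pseudogene or non-coding gene nearest. AC115970.1 was nearest to an intronic region with 41.7, and Gm43393 and Gm13191 to intergenic regions with 41.6 and 40.7. Gm11407 carried an exonic region with 31 and Gm13274 a promoter region with 29.8, and Gm47397 and Gm27679 were nearest to intergenic regions with 28.6 and 28. Of the 10, 4 aligned to the mitochondrial genome over more than 50% of their length. A median of 46.3% of the 31-base words of the 10 had another copy in the nuclear or mitochondrial genome.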

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

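The count of repeated words given here was chosen after the summits had been found. Of the 73889 summits that passed the IDR threshold of 0.05 in the ranked list that compares the replicates, 166 were absent from the conservative list, and 42 of these lay on sequences not placed on a chromosome. They stood out as peaks outside the list from which the report takes its regions, genes and motifs. The other 124 formed 44 regions on chromosomes. Among all 166 the strongest summit lay at chromosome 9, 24541943–24542233, with a fold enrichment of 44.4. A median of 24.2% of the 31-base words in the 44 regions had another copy in the nuclear or mitochondrial genome. In 10 regions at least 50% did. In 200 random reproducible regions the median was 0 and the mean 2.48%. Why these summits were absent was not tested, and no biological explanation was tested, since the design holds a single group.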

How the results depend on the processing

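Counting every summit, counting a region once per list, and random lists drawn without olfactory and vomeronasal receptor genes or also matched on neighbouring genes were chosen after the data were seen, and the other alternatives were planned. Replicate 1 kept more regions than replicate 2 under both alternatives, by 1.84 and 1.89 times. The IDR thresholded lists had 30964 regions in replicate 1 and 16822 in replicate 2, shared 52.3% and 97.6% of them, and left 1760 promoters open in replicate 1 only. Requiring an overlap of 50% of both regions gave shares of 41.1% and 70.6%. Equal numbers of regions gave 73.1% and 77.3%, with 488 promoters open in replicate 1 only and 546 in replicate 2 only. Spearman's rho was 0.680 at an IDR of at most 0.05 and 0.551 at distal summits. The promoter share was 47.9% with 1000 bp to either side of a TSS, 20.8% with replicated peaks, 54.7% at an IDR of 0.01 and 37.1% over every summit. It was 60.1% without replicate 1 and 38.2% without replicate 2, settings that use the IDR thresholded list of the other replicate. Lists with more distal regions than random lists numbered 5, 12 with replicated peaks, and from 4 to 7 elsewhere. Lists with fewer numbered 1, and 0 both without olfactory and vomeronasal genes and with each region counted once, where that receptor list was itself not tested. Lists with more open promoters numbered 2, 1 at an IDR of 0.01, 5 when matched on gene length alone, 1 without replicate 1 and 2 without replicate 2. The 1 list left at an IDR of 0.01 and without replicate 1 was the housekeeping genes, while mesenchyme and smooth muscle no longer passed. Lists with fewer numbered 5, 9 on length alone, 6 at an IDR of 0.01, 7 without replicate 1, and 4 without olfactory and vomeronasal genes, where the receptor list was not tested. Motifs below their shuffled versions numbered 3, 4 within 50 bp of the summits and 5 with promoters included, and motifs above them numbered 14, and from 12 to 14 elsewhere.

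Of 534 values of single lists and motifs under the alternatives, 445 kept their direction and side of the threshold, 31 passed it newly, 17 no longer passed it and 41 reversed. Passing values reversed in 4 cases. Anterior Hox genes fell from 3.24 to 0.926 times the distal regions of random lists when each region counted once, because their members share regions. Endothelial promoters went from 0.461 to 1.25 times random lists with replicated peaks. With promoters included, CTCF went from 1.60 to 0.726 and the proneural E-box from 1.11, which had not passed, to 0.914. CTCF still lay at more summits than flanks there, and the proneural E-box at about as many. Both motifs were thus lower than their shuffled versions only. The other reversed values passed neither as reported nor under the alternative. For distal regions within 10 kb they were leukocyte (0.898), nerve (1.85), cardiac (0.794), skeletal muscle (0.758) and germ cell genes (0.330), and within 100 kb forebrain genes (0.814). With replicated peaks they were liver (1.02), germ cell (0.948) and posterior Hox genes (1.35), and at an IDR of 0.01 mesothelial (0.796), liver (1.01) and germ cell genes (0.518). Counting every summit gave lung epithelial progenitor genes 0.974, airway 0.949, mesothelial 0.980 and forebrain genes 0.761, and counting regions once gave germ cell genes 0.975. Leaving out replicate 1 reversed progenitor (0.937), mesothelial (0.382) and germ cell genes (0.922). They kept their direction without replicate 2 (1.39, 1.14 and 1.06). Liver genes reversed without replicate 2 (1.24) but not without replicate 1 (0.849). At promoters, replicated peaks gave mesothelial genes 1.12, erythroid 1.65, anterior Hox 1.35 and retinoid, Notch and Hippo genes 1.07. An IDR of 0.01 gave progenitor genes 0.892, alveolar 0.893 and hedgehog, WNT, FGF and BMP genes 0.949. Length alone gave alveolar genes 0.892, anterior Hox 1.15 and retinoid, Notch and Hippo genes 1.32, the last at 1.03 when matched on neighbouring genes. Alveolar promoters stood at 0.995 with the wider promoter and at 0.985 without olfactory and vomeronasal genes. Progenitor promoters reversed without replicate 1 (0.979) but not without replicate 2 (1.04). The RUNX motif reversed without replicate 1 (0.952) but not without replicate 2 (1.09). The CRX and OTX motif reversed without replicate 2 (0.984) but not without replicate 1 (1.10). Apart from the anterior Hox genes and the receptor list, the cause was not tested. The read depth of the libraries is not given in the sources used here, so a region missing from one replicate was not detected there rather than shown to be closed.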

Other observations

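The gene families, the genes named within them, the test without the 2 leading photoreceptor genes and the split of the erythroid list were chosen after the data were seen. Among 16 families defined by gene symbol, collagen, integrin and semaphorin genes had about 2 times the distal regions of matched random lists. Collagen genes (44) had 1.70 per gene within 50 kb against 0.888 ± 0.187, with 5 each near Col14a1 and Col13a1, and 54.5% of their promoters were open against 52.6%. Integrin genes (27) had 1.85 against 0.908 ± 0.242, with 7 near Itga9, and semaphorin genes (20), which encode guidance cues, 2.25 against 1.01 ± 0.289, with 8 near Sema3f. The adjusted permutation p was 0.0016 for collagens and 0.002 for integrins and semaphorins. Laminin genes and ephrin and Eph receptor genes did not pass (1.57 and 1.53 times random lists, adjusted permutation p = 0.206 and 0.0855).

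Other families differed from random lists at promoters. Zinc finger genes (391) were open at 84.7% of promoters against 62.6% (adjusted permutation p = 8.0e-04), but had 0.770 distal regions per gene against 0.987 (0.004). Ribosomal protein genes were open at 93.4% against 82.8% and histone genes at 94.0% against 81.5% (adjusted permutation p = 0.0168 for both). Protocadherin genes were open at 13.2% against 53.1%, cytochrome P450 genes at 17.2% against 32.6%, keratin genes at 5.66% against 17.7%, and 0 of 64 defensin genes against 12.5% (adjusted permutation p of 8.0e-04, 0.00267, 0.0487 and 0.0064). Distal regions were more frequent near histone genes (2.09 times random lists) and less frequent near protocadherin (0.507) and defensin genes (0.258), with adjusted permutation p of 0.0016, 0.0114 and 0.0032. Genes of these last 3 families and keratin genes lie in clusters and can share regions, so their p-values can be too small. The same holds for any other family with clustered members, since no family was rerun with each region counted once. Solute carrier, Iroquois, Sox and T-box genes passed at neither promoters nor distal regions. The families were run with the conservative list alone.

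Replicate 1 had 82223 regions and replicate 2 had 47915, and why was left open. For lower detection in replicate 2 across the genome, 21 of 21 fixed lists had more than 50% of their summits stronger in replicate 1, but so did all their matched random lists, since replicate 1 was stronger at 79.7% of all summits, and this decides nothing. For a different mix of cell types in the pools, ranks of summits within each replicate were compared, and 3 of 21 lists lay outside the central 95% of matched random lists, where chance gives about 1: erythroid genes by −13.1 rank points of 100, leukocyte genes by −8.60 and anterior Hox genes by −8.05, all ranked higher in replicate 2. Of the 3, only the leukocyte list holds no shared summits. Its random range was −5.30 to 5.53, and 16 of its 18 genes had a negative difference. Anterior Hox genes count 146 distinct summits 461 times. Erythroid genes count 180 summits 206 times and without globins stood at −4.78, within their random range of −6.98 to 6.09. Among them, Hbb-bt, Hbb-bs and Hbb-y stood at −51.6 to −51.3, Slc4a1 at −21.5 and Hba-a1 at −1.34. The control list of olfactory and vomeronasal receptor genes lay outside its range the other way (0.837 against −2.07 to 0.424). It too shares summits, counting 713 of them 1298 times over the 310 genes with any. Each pool is 1 library, so whether the pools differed in cell types was not decided. No other biological explanation was tested.

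The 10 strongest reproducible regions may hold reads that belong elsewhere. Reads of mitochondrial DNA placed on nuclear copies were weighed by alignment, and 4 of the 10 regions aligned to the mitochondrial genome over at least 50% of their length, against 0 of 200 random reproducible regions. The strongest region aligned over 48.3% at 100% identity, and 5 regions did not align. Sequence present in more than 1 copy of the genome was weighed by 31-base words, and a median of 46.3% had another copy, against 0 in the random regions. Copies in the mitochondrial genome were counted too, so this value is not separate from the alignment. Regions that aligned to it had 41.4% to 76.3%, and the 5 that did not had 9.71% to 60.6%. The count of 4 regions and the median of 46.3% fell between the bounds set beforehand. Misplaced reads and open chromatin therefore cannot be told apart here without the reads, and no biological explanation was tested.

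Distal regions near photoreceptor genes were more frequent than in random lists although no photoreceptor promoter was open. Location among many neighbouring genes was tested by matching random lists on the number of genes within 50 kb as well. The excess kept a ratio of 2.29 (adjusted permutation p = 0.0253). The median number of such neighbours was 2 for the list and 2 for all protein-coding genes. These random lists still held olfactory and vomeronasal receptor genes, which have few distal regions, and the call was lost when those were left out. Both changes were not made together, so this was not decided. Over all alternatives run on distal regions the adjusted permutation p ran from 0.00165 to 0.245, and 4 of them lost the call. That 2 of the list genes carry the excess was tested by leaving the 2 genes with the most distal regions out of the list and of every random list alike. The other 11 had 0.909 per gene against 0.397 ± 0.253, 2.02 SD above random lists and a ratio of 2.29 (unadjusted permutation p = 0.0482). Some excess remained, but it barely cleared a bound of 2 SD set after the data were seen. Gnat1 had 8 and Rho 6 of the 24 regions, so how far these 2 genes carry the excess was not decided. No biological explanation was tested.

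Whether cell type motifs gather near cell type genes was tested in 56852 distal regions of the replicated list, as 5 hypotheses. The odds ratio was 1.03 for the ETS motif near endothelial genes, 1.16 for the forkhead motif and 1.23 for the NK2 motif near lung epithelial progenitor genes, 1.58 for the T-box motif near mesenchymal genes and 2.09 for the GATA motif near erythroid genes. None passed Fisher's exact test (smallest adjusted p = 0.630). With 2 to 16 matching regions per list, each upper 95% bound was 1.98 or more, so neither an excess nor its absence was shown.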
